A study of Homo sapiens with 4 samples.

How the data were processed

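MIA PaCa-2 cells, an established human pancreatic cancer line, were transfected with a miR-145 mimic or with a control scramble RNA, each at 50 nM. Total RNA was extracted 48 hours later with a QIAGEN RNeasy kit, per the labels' protocols. Each of 4 arrays received 150 ng of RNA labelled with Cy3. The titles name 2 control arrays and 2 miR-145 arrays, and these labels set the groups. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical. All 4 arrays lay on 1 slide read in 1 scan, with both control arrays in row 1 and both miR-145 arrays in row 2, so slide row and group cannot be told apart.

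The arrays were 1-colour Agilent human miRNA arrays, which carry several short DNA probes per mature miRNA, each printed at many spots. Per the file headers, Feature Extraction 10.5.1.1 gave each spot's brightness on a linear intensity scale after subtraction of a spatially detrended background, with no scaling between arrays. The deposited scanner files also hold raw mean, median and local background intensity per spot, a total signal per miRNA, and flags for outlier spots, saturation and signal well above background. The authors also deposited a value table and a table of their own comparison. Per the submitters' processing notes the tool was limma, and its version was not given in the sources used here. The deposited comparison table holds log2 fold changes with average log2 expression, p-values and adjusted p-values, and 2 scores, a moderated t and a log odds. Its direction is unstated, and its positive value for miR-145 was used to read it as miR-145 over control. The deposited value table tracked log2 of the raw median spot intensity (r of at least 0.9997 across probes within an array, slopes between 0.991 and 0.999), so its log2 scale was read from the values. Its column medians were 4.338 and 4.336 in the control arrays and 4.335 and 4.344 in the miR-145 arrays, and its largest value was the same on every array. Its normalization and centring stay unknown. All 851 fold changes of the authors' comparison table equalled a difference of group means of 1 probe in the value table within 1e-04 on the log2 scale.

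Here the background-subtracted brightness of non-control spots without outlier flags was averaged per probe. Each array was divided by its 75th percentile over the 300 probes well above background on all 4 arrays, relative to the geometric mean of these percentiles, then floored at a scaled brightness of 1 and taken to log2. A probe counted as well above background where over 50% of its spots carried that flag. A miRNA was read by its brightest probe, the one with the highest mean over the 4 arrays regardless of group. It was kept if a probe was well above background on at least 2 arrays of any group, which left 202 of 939 miRNAs. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only), with Benjamini-Hochberg adjustment over the 202 miRNAs and a threshold of 0.05. Levels are given as mean ± SD of 2 arrays on the log2 scale, and the small number of arrays limits their precision. No exact permutation test could pass, since 2 arrays against 2 give a smallest two-sided p of 0.333. Probe names and miRNA names are those of the array design, in the older style in which an asterisk marks the less abundant strand of a precursor. Whether current annotation still lists each of them as a miRNA was not checked.

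Where a miRNA was not well above background on either control array, its rise is given as "at least N-fold". This sets the mean of the miR-145 arrays against the mean of, per control array, the higher of the dimmest probe well above background and the miRNA's own brightness. The log2 fold changes and p-values of such miRNAs depend on the floor. Where both control values were set to the floor, as for miR-124, the control SD of 0 is not a measured spread.

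Before the data were examined, 19 lists of miRNAs were fixed: the miR-143/145 cluster, the miR-200, let-7, miR-15/16, miR-29 and miR-30 families, the miR-17 and miR-23/27/24 clusters, p53-responsive miRNAs, miRNAs reported as raised in pancreatic cancer, innate immune and pluripotent stem cell miRNAs, markers of other cells (acinar and islet, fibroblast and smooth muscle, blood, and muscle, liver and neuron), G-rich or poorly supported miRNAs that often move together on arrays, passenger strands and viral miRNAs. miR-145 was left out of every list test. The 12 lists with at least 3 kept members were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists. The miRNAs named were fixed by rule: miR-145, miR-145*, miR-143 and miR-143*, the 12 largest rises and 12 largest falls among those past the threshold with no overlap between groups, filled up by unadjusted p, up to 4 of the brightest and up to 4 more called members of each list, and the 5 brightest miRNAs. Names outside that rule are said to be so.

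The alternatives changed 1 choice at a time: scaling, background correction (normexp, offset 50), the summary over probes, the source of values, the filter, the floor (4 times higher), the variance model, the threshold, outlier flags, the replicate number as a block, and leaving out each array. Scaling to 3 sets of positive control probes (hur_2, hur_4 and hur_5) and camera on ranks were added after seeing the data. On simulated data for the 202 miRNAs, with 20 changed per size in each of 50 simulations, the limma step called 88.7% of changes of 0.5 on the log2 scale, 99.6% of changes of 1 and all of 2, and 4.50% of its calls were false on average. In simulated lists of 21 miRNAs, camera gave an unadjusted p under 0.05 in 2% of 50 unshifted lists. Noise was drawn independently for each miRNA from the variances that limma fitted to these arrays. No effect shared by an array was simulated, and the scaling, floor and filter were left out. The simulations therefore cannot show limma's error rate where those matter, nor how camera behaves on lists whose members are correlated. Duplex energies came from RNAduplex of ViennaRNA 2.7.2, and plots from matplotlib 3.10.9 in Python 3.11.15. The DNA probes were entered as RNA, so these energies only approximate those of DNA probes with RNA on the array.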

Results

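The arrays measured mature miRNAs in MIA PaCa-2 pancreatic cancer cells 48 hours after transfection of a miR-145 mimic or a control scramble RNA, with 2 arrays in each group. Each array carried 2689 probes for 939 miRNAs, of which 851 were human and 88 viral. Signal well above background was found for 176 and 188 miRNAs on the control arrays and for 204 and 203 on the miR-145 arrays. No spot was saturated, and 6.18% to 6.86% of the spots carried an outlier flag. Across the 202 kept miRNAs, which are not independent replicates, log2 levels correlated at 0.997 between control arrays and at 0.998 between miR-145 arrays. Between groups they correlated at 0.861 to 0.868, with miR-145 and the miRNAs at the floor in control included. The median absolute log2 difference was 0.10 between the control arrays, 0.08 between the miR-145 arrays and 0.18 to 0.22 between groups. The brightest miRNAs, by the names of the array design, were miR-720, miR-21, miR-886-3p, miR-1274b and let-7i. miR-21, an abundant miRNA of many tumours, had a log2 level of 12.89 ± 0.13 (SD, n = 2) in control and 12.92 ± 0.07 (SD, n = 2) in miR-145 arrays. None of these 5 passed the limma test, and their log2 differences ran from -0.11 for miR-886-3p to 0.18 for miR-1274b. The signs of miR-720, let-7i and miR-1274b turned negative, past the threshold, in the authors' processed values. That of miR-21 did so in the authors' deposited table (-0.30, limma adjusted p = 0.0028). The table holds 1 probe per miRNA, and its average log2 level of 9.72 for miR-21 may be that of another probe.

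The level of the transfected miRNA was examined first. miR-145 was not well above background on either control array, and its brightest probe read 0.393 and 1.52 units of scaled brightness there. On the miR-145 arrays the same probe read 7418 and 8200 units. The rise was at least 1404-fold, and the fitted log2 difference was 12.63 with a standard error of 0.18 (limma adjusted p = 6.0e-10). The brightest probe, AGGGATTCCTGGGAAAA, is complementary to the 3′ end of mature miR-145. The array design places it on chromosome 5 from 148810231 to 148810246. The file headers name hg18, and the build of these mapped positions could not be checked here. An overlapping probe, AGGGATTCCTGGGAAAAC, read 2.34 and 1.45 units on the control arrays and 7035 and 7859 on the miR-145 arrays. The opposite strand of the precursor, miR-145*, and its genomic neighbours miR-143 and miR-143* were not well above background on at least 2 arrays and were not tested. The authors' deposited table gives miR-145 a log2 fold change of 8.52.

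**Figure D1:**
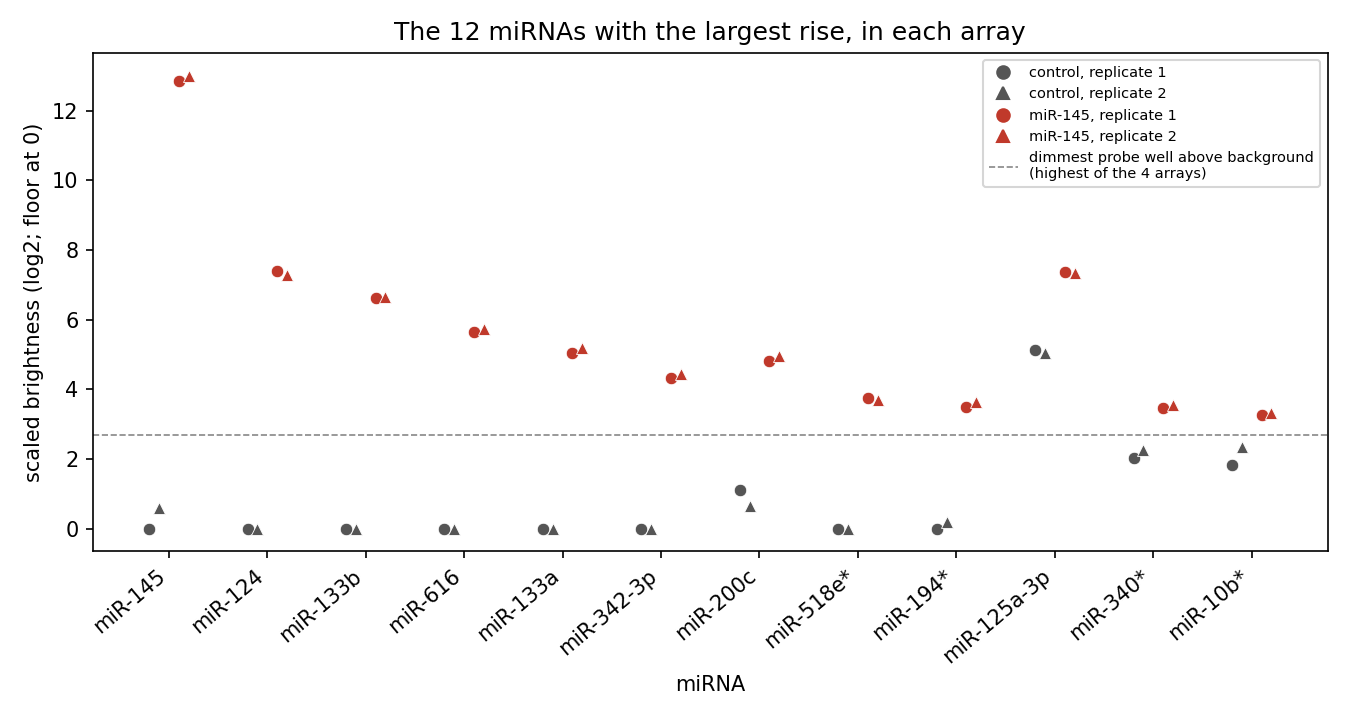
Log2 scaled brightness (vertical axis, floor at 0) of the 12 miRNAs with the largest rise (horizontal axis) on each control array (grey) and miR-145 array (red), with replicates 1 and 2 as circles and triangles. The dashed line is the dimmest probe well above background, taken from the array where it is highest. Of the 12, only miR-125a-3p lies above that line on the control arrays.

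The main question was which other miRNAs differed after miR-145 transfection. Several miRNAs that were not well above background in control cells were well above it on both miR-145 arrays. miR-124, which is abundant in neurons, reached a log2 level of 7.34 ± 0.07 (SD, n = 2) and rose at least 29.1-fold (limma adjusted p = 3.8e-10). Both its control values were set to the floor, so this p-value depends on the floor. The muscle miRNAs miR-133b and miR-133a rose at least 17.9-fold and 6.21-fold, to log2 levels of 6.63 ± 0.02 and 5.11 ± 0.11 (SD, n = 2). These have nearly identical sequences, and their probes may share signal. miR-616 rose at least 9.32-fold, miR-200c, an epithelial miRNA that represses ZEB1 and ZEB2, at least 5.33-fold, and miR-342-3p at least 3.77-fold. The passenger strands miR-518e*, miR-194*, miR-340* and miR-10b* rose at least 2.39-fold, 2.13-fold, 2.04-fold and 1.72-fold. Of these, miR-10b* alone did not pass in every other scaling. The largest rise of a miRNA detected on all 4 arrays was that of miR-125a-3p, from a log2 level of 5.08 ± 0.06 to 7.34 ± 0.02 (SD, n = 2), a 4.78-fold difference (limma adjusted p = 3.0e-07).

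Falls were smaller. Among the 11 miRNAs that fell, miR-149 decreased by 0.61 on the log2 scale (SE 0.09, limma adjusted p = 0.0021), from 5.60 ± 0.03 to 4.98 ± 0.10 (SD, n = 2). It was followed by miR-324-5p, which fell by 0.45, miR-501-3p by 0.44, miR-99b by 0.42, miR-148a by 0.41, let-7e by 0.41 and miR-769-5p by 0.40. miR-1308, miR-24, miR-331-3p and the hypoxia-responsive miR-210 fell by 0.32, 0.31, 0.30 and 0.29. miR-886-5p, next by unadjusted p, had a log2 difference of -0.30 and did not pass the adjusted threshold (limma adjusted p = 0.050). The falls of miR-501-3p and miR-148a turned to small positive values, 0.090 and 0.042, under normexp background correction, and that of miR-501-3p also turned with Agilent's total signal per miRNA (0.038) and with the mean of all probes (0.15).

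In all, 55 of the 202 miRNAs passed limma's test, 44 raised and 11 lowered, and 79 had an unadjusted p under 0.05. The rise was at least 2-fold in the fit for 12 miRNAs, and no fall reached that size. Of the 55, 15 (miR-145 among them) were not well above background on either control array and were well above it on both miR-145 arrays, and 0 went the other way. The groups did not overlap for all 55 and for 65.8% of the 202, where chance gives 33.3% for a single miRNA. All 202 miRNAs were read on the same arrays, so a shift shared by an array can separate many of them at once. The 65.8% therefore cannot show how many miRNAs changed separately. The 55 were picked by their difference between groups, so their lack of overlap is no separate check. A second detected probe was present for 37 of the 55, and 0 of these had the opposite sign. Probes of the same miRNA can overlap in sequence, as those of miR-145 do, and read the same molecules. Their agreement is therefore not an independent check.

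The split between rises and falls depended on the scaling. Raised miRNAs made up 80% of the calls with the main scaling, 61.7% with the median of detected probes, 36.4% with the 75th percentile of all probes, 24.8% without scaling, 24.7% with quantile normalization and 25.0% with positive control probes. The 75th percentile of all probes falls among probes not well above background, as only 310 to 352 of the 2689 probes on each array were well above it. Results with that scaling therefore depend on dim probes. Without scaling the median log2 difference of the 202 miRNAs moved from 0.06 to -0.22, so the fold changes here are relative to the detected miRNAs. In 5 scalings other than the main one, 27 of the 55 calls (16 raised, 11 lowered) passed in every one, and none of the 55 changed sign. These scalings are not independent checks. The median log2 difference was -0.22 without scaling, -0.22 with the 75th percentile of all probes and -0.19 with positive control probes. Without miR-145 replicate 1 or replicate 2, where the lone array is assumed to vary like the control arrays, 11 and 9 miRNAs passed.

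**Figure D2:**
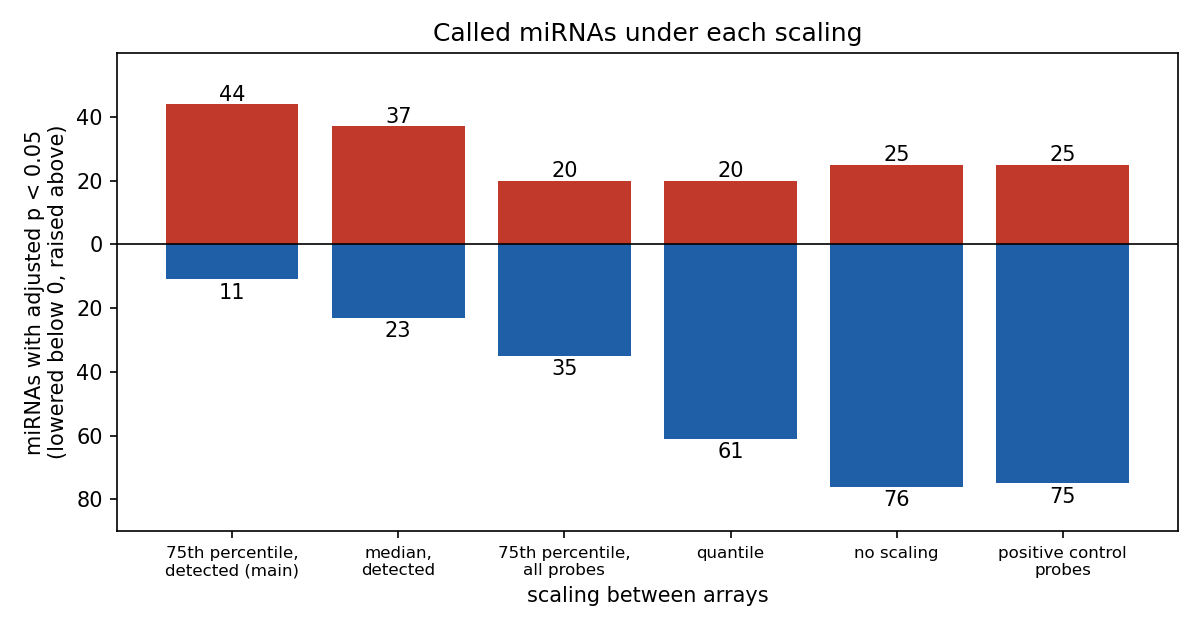
Number of miRNAs with a limma adjusted p under 0.05 (vertical axis, raised in red above 0 and lowered in blue below 0) under 6 ways of scaling the arrays (horizontal axis). The main scaling gives 44 raised and 11 lowered miRNAs, and no scaling gives 25 raised and 76 lowered.

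The fixed lists showed which groups of miRNAs these were. Of the 9 members of the muscle, liver and neuron list, 4 were kept and 3 rose, miR-124, miR-133a and miR-133b, while miR-128 had a log2 difference of -0.19. The 3 that rose passed the filter through the miR-145 arrays alone, and miR-133a and miR-133b may share signal. Camera's p-values for this list rest on these 3, so they are no separate test of muscle or neuron miRNAs as a group. The list's median log2 difference was 5.87, or 3.40 with the 3 members not well above background in control arrays at their bounds (camera adjusted p = 0.0038, and adjusted p = 0.68 with an estimated correlation). Adjusted over the list alone, the same number rose. Without miR-145 replicate 2, camera gave an adjusted p of 0.054 for this list. The other lists of markers of other cells had few kept members. The acinar and islet list kept miR-7 (log2 difference 0.15), the blood list kept miR-126 (-0.13) and miR-486-5p (-0.19), and the fibroblast and smooth muscle list kept only miR-145 itself. None of miR-7, miR-126 and miR-486-5p passed.

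Of the 21 kept miRNAs on the list of G-rich or poorly supported species, 14 rose and 0 fell, and 14 rose adjusted over the list alone. They included miR-125a-3p, miR-1225-5p (log2 difference 0.95), miR-1915 (0.70), miR-1207-5p (0.65) and miR-638 (0.63). Of these, miR-1915, miR-1207-5p and miR-638 did not pass in every other scaling. With the 75th percentile of all probes, 3 of the 21 rose and 0 fell. The list's median was 0.46 (camera adjusted p = 0.0038, and adjusted p = 0.82 with an estimated correlation), and the list did not pass fry (adjusted p = 0.081). The list's median lay 0.43 above that of the other kept miRNAs with quantile normalization, the only one of the 5 other scalings that can change this gap. Camera's adjusted p was 0.00031 without scaling, 4.2e-05 with quantile normalization, 9.9e-05 with positive control probes and 0.0020 with the median of detected probes. But it was 0.69 with the 75th percentile of all probes, a scaling set among probes not well above background. Without control replicate 1 the adjusted p was 0.070, and without scaling 7 of the 21 rose and 0 fell.

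Of 25 kept passenger strands, 11 rose and 0 fell, and adjusted over the list alone 15 rose and 1 fell. Of the 25, 6 were not well above background on either control array and passed the filter through the miR-145 arrays alone. With the filter on all 4 arrays the list had 17 members, a median of 0.14 and a camera adjusted p of 0.42. miR-99b* rose by 0.80 on the log2 scale, miR-373* by 0.52, miR-629* by 0.40 and miR-21* by 0.30, while the guide strand miR-99b fell. Without scaling miR-99b* still passed (0.51), and miR-373* (0.24), miR-629* (0.11) and miR-21* (0.02) did not. The list did not pass camera (median 0.30, adjusted p = 0.060, and adjusted p = 0.68 with an estimated correlation), but it passed camera without scaling (adjusted p = 0.019), where 7 rose and 5 fell, with quantile normalization (0.041), positive control probes (0.017), the authors' processed values (0.016) and normexp (0.0065), though not with the 75th percentile of all probes (0.69), and it passed with fry, which does not compare it with other miRNAs (adjusted p = 0.0023). Of 3 viral miRNAs above background, hcmv-miR-UL70-3p rose by 0.83 and kshv-miR-K12-3 by 0.46, while ebv-miR-BART13 had a log2 difference of -0.09. Both rose adjusted over the list alone, and the list did not pass camera (adjusted p = 0.40). Without scaling kshv-miR-K12-3 did not pass (log2 difference 0.17), and 1 of the 3 rose, as with the 75th percentile of all probes, quantile normalization and positive control probes.

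The large families of the line showed few calls. Of 9 kept let-7 miRNAs, which have near-identical sequences and may share signal, only let-7e fell, and the bright members let-7a, let-7b and let-7d had log2 differences of -0.04, 0.07 and -0.08. Let-7i and let-7b turned negative in the authors' deposited table, where both had adjusted p under 0.05. For let-7b the table may read another probe (average log2 level 8.03). None of 11 kept members of the proliferation-linked miR-17 clusters passed limma's test. miR-20a, miR-106b, miR-19b and miR-25 had differences of 0.23, 0.05, 0.15 and 0.06, and the near-identical miR-17, miR-20a and miR-106b may share signal. In the miR-15/16 family, 1 of 6 rose, miR-195 by 0.40, while miR-15b, miR-16 and miR-15a had differences of -0.06, 0.17 and 0.07. miR-195 had the opposite sign (-0.027) in the authors' deposited table. In the miR-23/27/24 clusters, 1 of 5 fell, miR-24, and miR-27a, miR-23a and miR-27b had differences of 0.01, 0.01 and -0.16. None of the 3 kept miR-29 and 5 kept miR-30 miRNAs passed, and their brightest members, miR-29a and miR-30a, had differences of 0.14 and 0.14. These counts held when adjusted over each list alone. The 6 lists did not pass camera, with adjusted p between 0.29 and 0.99. Under normexp background correction the let-7 family and the miR-23/27/24 clusters passed it as lowered (adjusted p = 0.0065 and 0.042). Without scaling, where the median of all kept miRNAs was lower, 5 of the 9 let-7 miRNAs, 2 of the 11 in the miR-17 clusters, 2 of the 6 in the miR-15/16 family, all 5 in the miR-23/27/24 clusters and 1 of the 5 miR-30 miRNAs passed as lowered, and miR-195 did not pass.

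Among 7 kept miRNAs of the pancreatic cancer list, only miR-210 fell, and it did not pass when adjusted over the list alone. miR-21, miR-10a and miR-221 had differences of 0.03, -0.12 and -0.13. None of the 3 kept p53-responsive miRNAs passed, and miR-107, miR-192 and miR-34a had differences of -0.21, 0.01 and -0.22. Neither list passed camera (adjusted p = 0.31 for both). Without scaling, 4 of the 7 and all 3 passed as lowered. Of the miR-200 family only miR-200c was kept. The innate immune list kept miR-132 (-0.05) and the pluripotent stem cell list miR-371-5p (0.18), and neither passed. Without scaling miR-132, miR-126 and miR-486-5p passed as lowered, as did miR-128.

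**Figure D3:**
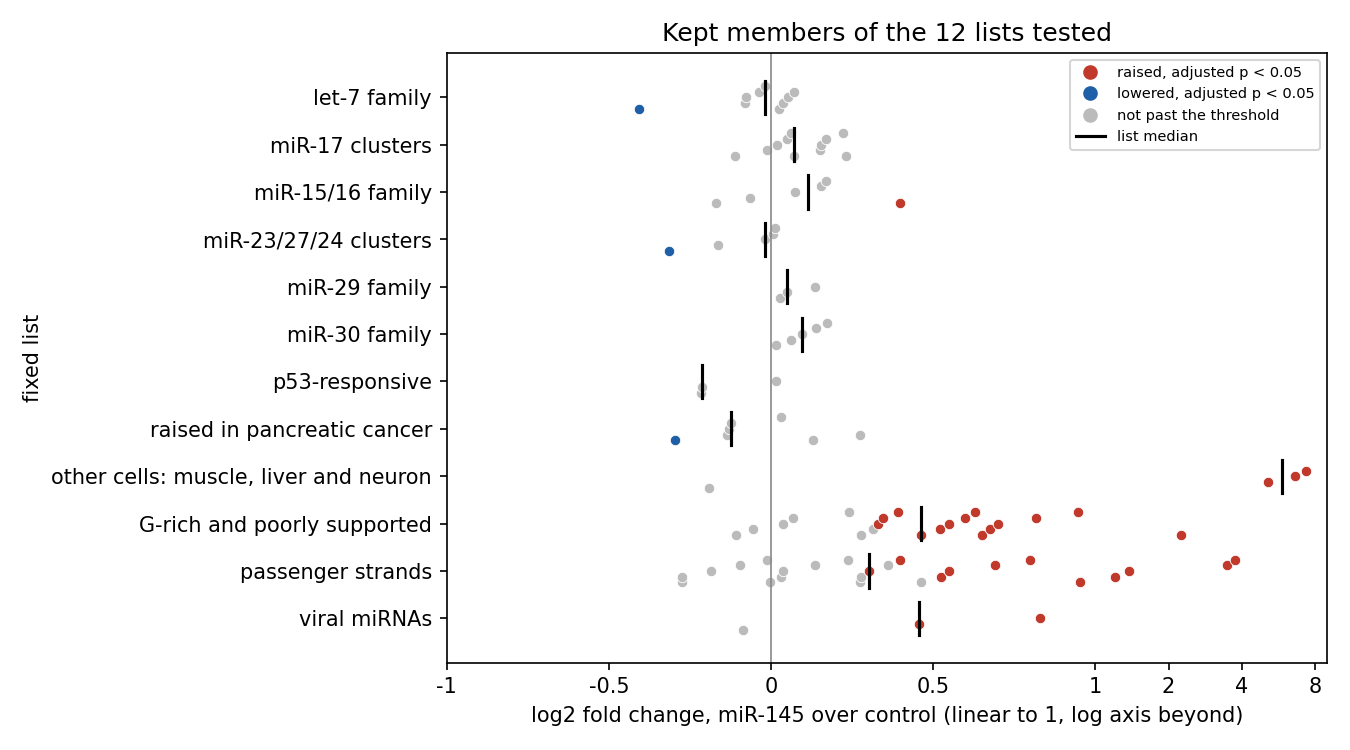
Log2 fold change of miR-145 over control arrays (horizontal axis, linear up to 1 and a log axis beyond) for each kept member of the 12 lists tested (vertical axis). Points are miRNAs, red or blue where limma's adjusted p was under 0.05 and grey otherwise, and bars are list medians. Most rises lie in the G-rich list, with 14 of 21 members, and among passenger strands, with 11 of 25.

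The authors' deposited table lists 851 human miRNAs, 120 of them with adjusted p under 0.05, 46 raised and 74 lowered. It shares 199 miRNAs with the kept set, and the sign of the log2 fold change was the same for 133 of these (Pearson's r = 0.912, Spearman's rho = 0.865 across miRNAs, which are not independent replicates). Of the 53 miRNAs called here that the table lists, 30 passed in both, all 30 with the same sign. The table's 1 probe per miRNA was not always the brightest. For miR-720 it gives -0.58, where the brightest probe in the authors' processed values gives -0.44.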

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

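The tests of muscle or neural RNA, of locus transcription and of the G-rich list (scaling, probe GC content and length, and signal level) were chosen after the results were seen, as was the matching on GC content. Outside the main measurement, 2 sets of control probes, of those over 10 units on every array, were brighter on both miR-145 arrays than on both control arrays. The set named hur_6 read 1.19 times its control mean, and the set named SCorner3 read 1.08 times. Other bright sets moved the other way, to 0.760 times for mr_1, 0.916 times for miRNABrightCorner30, and 0.973, 0.986 and 0.987 times for hur_2, hur_4 and hur_5.

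The first pattern is the 14 miRNAs besides miR-145 that were not well above background on either control array and rose on both miR-145 arrays, miR-124 and miR-133b foremost. RNA from muscle or neural cells is argued against by 4 of the 5 other listed miRNAs of those cells. These, miR-1, miR-206, miR-9 and miR-219-5p, were not well above background on either miR-145 array (miR-122, of liver, was dropped from an earlier count). The case is weaker for muscle. miR-1 and miR-206 moved from log2 levels of 0 and 0.07 in control to 1.26 and 1.13, too dim to be tested. miR-9 stayed at 0 and miR-219-5p read 0.09 on the miR-145 arrays. Transcription of the 14 miRNAs' own loci stays open. Of 12 other arms or cluster partners, 0 were well above background on both miR-145 arrays, but none was bright enough to be tested. The other arm of a precursor is often degraded. That does not account for the cluster partners miR-1, miR-206 and miR-141. Nor does it account for miR-518e, miR-194, miR-340, miR-10b and miR-187, the arms without an asterisk opposite risen passenger strands. Hybridization of the transfected strand or its complement to the probes of the 14 miRNAs stays open. Their median duplex energy, with the probes taken as RNA, was -9.75 kcal/mol. This was stronger than in 95.9% of 10000 random probe sets matched on length, past the bound set before that test was run. With matching on GC content too, chosen later, the median energy was stronger than in only 91.8%, which is not past that bound. miR-124's own probe reached only -5.0. A response of the cells to miR-145, or traces of other synthetic miRNAs, may also account for them, and neither was tested.

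The second pattern is the joint rise of the G-rich or poorly supported list. Each SE below is the SD over list members divided by the square root of their number. It treats the members as independent and leaves out the error of the other miRNAs, so it may be too small. Scaling between arrays is argued against for the rise against the other miRNAs, since a factor per array moves all alike and the gap of the medians was 0.43 (SE 0.11) with quantile normalization, which can change it, but the size of the rise stays open, as the list's median was 0.18 (SE 0.11) without scaling. After a robust line on signal level was removed, the median stayed at 0.39 (SE 0.11). This argues against a trend with level as the whole cause only as far as that SE holds. A trend with probe GC content and length stays open: an ordinary line without the 14 miRNAs above, run first, left 0.32 (SE 0.11), just past a bound of 0.1 by over 2 SE, but it left out miRNAs that had passed the test, and the robust line with them left 0.27 (SE 0.11), which is not past it. A response to miR-145 stays open and untested.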

How the results depend on the processing

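Scaling to positive control probes and camera on ranks were chosen after seeing the data. miR-145 passed limma's test under every alternative that tested it, with log2 differences from 7.09 (normexp) to 12.93. Of the 55 calls, 8 held their sign and passed in every fit that tested them, miR-125a-3p in all 20 and the other 7 in 19, since the filter on all 4 arrays left them out: miR-145, miR-124, miR-133b, miR-616, miR-133a, miR-342-3p, miR-518e* and miR-125a-3p. The count of 55 became 101 without scaling, 129 with normexp, 83 with Agilent's total signal, 100 with positive control probes, 27 with a fold of at least 1.5, and 8 without a filter on dim probes. Leaving out 1 array gave 9 to 65 calls, and the low counts came without a miR-145 array. The causes were not tested. With the replicate number as a block the count was 76, all 55 among them. The numbers are not shown to pair the arrays: the replicate differences of the 2 groups correlated at r = 0.43 (Spearman's rho = 0.38) across 202 miRNAs, with 2 pairs only. The 2 lists past camera became 1 with the 75th percentile of all probes (the G-rich list lost), 3 without scaling, with quantile normalization, with positive control probes and in the authors' processed values (passenger strands gained in each), 5 with normexp (let-7 and miR-23/27/24 lowered and passenger strands raised in addition), 1 with the filter on all 4 arrays (the muscle, liver and neuron list could not be tested), 1 with the block (the G-rich list lost, adjusted p = 0.25), 0 with an estimated correlation, 1 on ranks (the muscle, liver and neuron list lost), 2 with fry (the G-rich list lost and passenger strands gained), and 1 to 2 without 1 array. The median log2 difference of the kept miRNAs moved by -0.28 without scaling, -0.29 with the 75th percentile of all probes, -0.21 with quantile normalization, -0.26 with positive control probes, -0.16 in the authors' values and 0.12 with total signal. The 75th percentile of detected probes fell by 0.28 on the log2 scale, and the positive control sets hur_2, hur_4 and hur_5, used for scaling, fell by 0.026. The sets mr_1 and miRNABrightCorner30, at 0.760 and 0.916 times their control means, were not used for scaling. Nor were hur_6 and SCorner3, at 1.19 and 1.08 times.

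Signs turned, with a pass before or after, as follows, and the cause was not tested beyond the shift of the median. Without scaling: miR-27a -0.27, miR-23a -0.28, miR-30b -0.27, miR-192 -0.27 and miR-30a* -0.26. With quantile normalization: let-7i -0.50, miR-106b -0.24, miR-27a -0.39, miR-23a -0.25, miR-30b -0.19, miR-192 -0.18 and miR-1274b -0.55. With normexp: miR-501-3p 0.090, miR-148a 0.042, miR-34a 0.11, miR-132 0.13 and miR-1914* 0.12. miR-501-3p was 0.038 with total signal and 0.15 with the mean of all probes. In the authors' processed values: let-7i -0.39, miR-106b -0.23, miR-195 -0.0024, miR-27a -0.33, miR-23a -0.29, miR-30b -0.16, miR-192 -0.12, miR-720 -0.44 and miR-1274b -0.57. With positive control probes: miR-25 -0.20, miR-27a -0.25, miR-23a -0.25, miR-30c -0.20, miR-30b -0.24, miR-192 -0.24 and miR-30a* -0.23. In the authors' deposited table, which does not always read the brightest probe: let-7i -0.39, let-7b -0.30, miR-106b -0.23, miR-195 -0.027, miR-27a -0.33, miR-23a -0.29, miR-21 -0.30, miR-720 -0.58 and miR-1274b -0.57. Sign changes of values that never passed were only counted, 151 of 1529 comparisons. Signal over background limits the folds of miRNAs not well above background in control cells to bounds.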

Other observations

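Some miRNAs outside the naming rule, chosen after their values were seen, also passed limma's test. miR-152 rose at least 1.74-fold from a level not well above background on both control arrays (limma adjusted p = 0.00030), while miR-148a, of the same family, fell. miR-134 rose by 0.82 on the log2 scale, and miR-193a-3p rose by 0.32 but did not pass in every other scaling (0.04 without scaling). Values in the cluster that encodes miR-99b, let-7e and miR-125a were also looked up afterwards, with no test of the cluster as a group. miR-99b and let-7e fell by 0.42 and 0.41 on the log2 scale, and miR-125a-5p had a log2 difference of -0.29 that did not pass (limma adjusted p = 0.056), while miR-99b* and miR-125a-3p rose by 0.80 and 2.26. let-7e* was not kept and was not tested. The falls of miR-99b and let-7e and the rise of miR-125a-3p passed in each of the 5 other scalings, and the rise of miR-99b* did not.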
